A study of Drosophila melanogaster with 5 samples.

How the data were processed

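Total RNA from pupal heads (80 h after pupa formation, 15 to 20 heads per sample) was labelled with biotin and hybridised to an Affymetrix Drosophila array, 1 array per sample. The deposited values are signal intensities that the authors computed with MAS5, on a linear scale and already scaled between arrays. The sources used here give no version or settings for MAS5, no target of the scaling and no detection calls. MAS5 combines perfect-match and mismatch probes, so dim probe sets carry mostly background and vary most on a log scale. The mean signal with 2% trimmed at each end was 105 and 106 on the Canton S arrays and 96.9, 103 and 99.4 on the otd-uvi arrays.

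Samples were grouped by strain, 2 Canton S arrays against 3 otd-uvi arrays. The replicate numbers were treated as labels only. Of the probe sets, 44 controls were left out of the tests and 13966 were tested. A reference table of array annotation gave 1 gene for 12443 probe sets, several for 327 and none for 1196. Names of 12394 single-gene probe sets were brought up to date by gene identifier, and 49 kept the name in the table. No genome build is named with the data, so positions are not given. A probe set was taken to be under the controls in a group when no array of that group exceeded the brightest of its 8 mouse and yeast controls.

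Signals were analysed as log2(signal + 8), where 8 is the rounded 20th percentile of all signals. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with strain as the only term, and p-values were adjusted by Benjamini-Hochberg over 13966 probe sets, with a threshold of 0.05. Log2 differences are otd-uvi minus Canton S, with moderated standard errors and 95% intervals. The residual degrees of freedom were 3 and limma's prior added 4.16. The pipeline was tested on simulated data with the same number of arrays and a spread drawn from limma's prior. The 200 changed probe sets were drawn from the brighter ones only, and no shift with signal was simulated. Of those with a log2 difference of 1, 22% were recovered, and of those with 2, 84%, and 10 of 116 calls were false. The shares recovered do not cover dim probe sets.

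Before the data were examined, 25 gene lists were fixed: phototransduction, rhodopsins, retinoid handling, rhabdomere, eye pigment, lens and cone cells, eye transcription factors, histamine and synapse, neurons, glia, muscle, fat body, hemocytes, antennal chemosensory genes, sex-linked expression, ecdysone response, cuticle, heat shock, antimicrobial response, clock, cell death, cytochrome P450s, glutathione S-transferases, ribosomal proteins and the proteasome. The 24 lists with at least 5 measured genes were tested with camera in limma, with a preset correlation of 0.01 between genes, 1 probe set per gene (the one with the highest mean) and Benjamini-Hochberg adjustment over the 24 lists. The alternative estimated the correlation from the data. Counts were also adjusted over each list alone. Older names on the lists were matched to current symbols by hand, and listed genes without a probe set of their own were left out. The share of called genes in each list was compared with that of other genes by Fisher's exact test, which was added after seeing the data.

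The rule for named genes was set at the same time. It took oc and each measured rhodopsin; the 12 largest rises and the 12 largest falls among called probe sets that did not overlap between groups and named 1 gene; each list member past the threshold; and up to 4 members with the largest absolute difference for each list discussed. Arr1, trpl and Gbeta76C, and genes marked as such in the text, were chosen outside this rule after their values were seen.

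Alternatives planned before the data were examined were quantile normalization, median centring, a floor at the 1st percentile in place of the pseudocount, a pseudocount 4 times larger, leaving out the dimmest 40% of probe sets, no intensity trend, array weights, the replicate number as a block, leaving out each array, camera with an estimated correlation, and the mean of all probe sets of a gene. Cyclic loess and a covariate for RNA integrity (the mean log2 ratio of 3-prime to 5-prime signal of the actin, GAPDH and eIF-4a controls) were added after seeing the data. Without 1 Canton S array the other is assumed to vary as the otd-uvi arrays do.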

Results

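Gene expression was measured in heads of Drosophila melanogaster pupae, 80 h after pupa formation, when photoreceptors were completing their differentiation. Canton S, a wild-type laboratory strain, gave 2 arrays, and the mutant strain otd-uvi gave 3, each from a separate RNA extraction of 15 to 20 heads. The labels describe otd-uvi as an eye-specific mutant allele. The affected gene, oc (orthodenticle, otd), encodes a homeodomain transcription factor related to vertebrate CRX and OTX. The array carried 13966 probe sets besides its controls, and 12443 of them named 1 gene each, for 10844 genes. The median signal was 41.3 and 39.96 on the Canton S arrays and 43.1, 42.8 and 41.8 on the otd-uvi arrays. Log2 signals correlated across probe sets at 0.953 to 0.966 between arrays of 1 group and at 0.930 to 0.955 between arrays of different groups. Probe sets are not independent replicates. The number of arrays limits the precision of every value below, where means are given with the SD over 2 Canton S and 3 otd-uvi arrays.

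The arrays of the 2 groups also differed in their control signals. Mouse and yeast control probe sets, which have no target in fly RNA, had a median signal of 7.39 ± 0.472 in otd-uvi and 3.38 ± 0.434 in Canton S (exact permutation test, two-sided p = 0.1, the smallest that 5 arrays allow). Dim probe sets as a whole had higher values in otd-uvi and bright ones lower values: the median log2 difference was 0.28 in the third decile of mean signal and -0.13 in the ninth. The log2 ratio of 3-prime to 5-prime signal is a sign of RNA degradation when high. It averaged 1.79 ± 0.317 in otd-uvi and 1.35 ± 0.143 in Canton S for the eIF-4a control (exact permutation test, two-sided p = 0.3). For GAPDH it averaged 1.74 ± 0.256 against 1.56 ± 0.235 (exact permutation test, two-sided p = 0.5). For actin the ratios overlapped, at 1.38 and 1.12 in Canton S and 1.06, 1.34 and 1.64 in otd-uvi (exact permutation test, two-sided p = 0.8). The mean of the 3 controls was 1.41 and 1.37 in Canton S and 1.32, 1.68 and 1.88 in otd-uvi (exact permutation test, two-sided p = 0.4).

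The comparison of otd-uvi with Canton S asked which genes of the developing head depend on Otd. Of 21 measured phototransduction genes 4 fell in otd-uvi, Arr2, trp, inaD and Cds, and so did chp, which encodes a membrane protein of the photoreceptor. Genes of detoxification moved in both directions, with a nearly complete loss of signal for Cyp6a17 and a rise for GstE1. At an adjusted p under 0.05 in limma, 45 probe sets rose and 63 fell, 108 in all, and 41.7% of these rose. None of the 108 overlapped between groups on any array, whereas 34.0% of all probe sets did not overlap and chance gives 20%. The called probe sets that named a single gene covered 94 genes, 40 higher and 54 lower. An unadjusted p under 0.05 was reached by 2100 probe sets, where chance gives 698, and an adjusted p under 0.1 by 272. The count rested on all 5 arrays: it was 3 without Canton S replicate 1, 2 without Canton S replicate 2, and 18, 22 and 8 without otd-uvi replicates 1, 2 and 3. It was 8 with the 3-prime to 5-prime ratio as a covariate. Of 46 genes that are named for comparison and did not pass, 21 moved by over 1.5 times on the log2 scale without 1 array. Each group was 1 strain, so differences of strain background are part of every value.

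**Figure D1:**
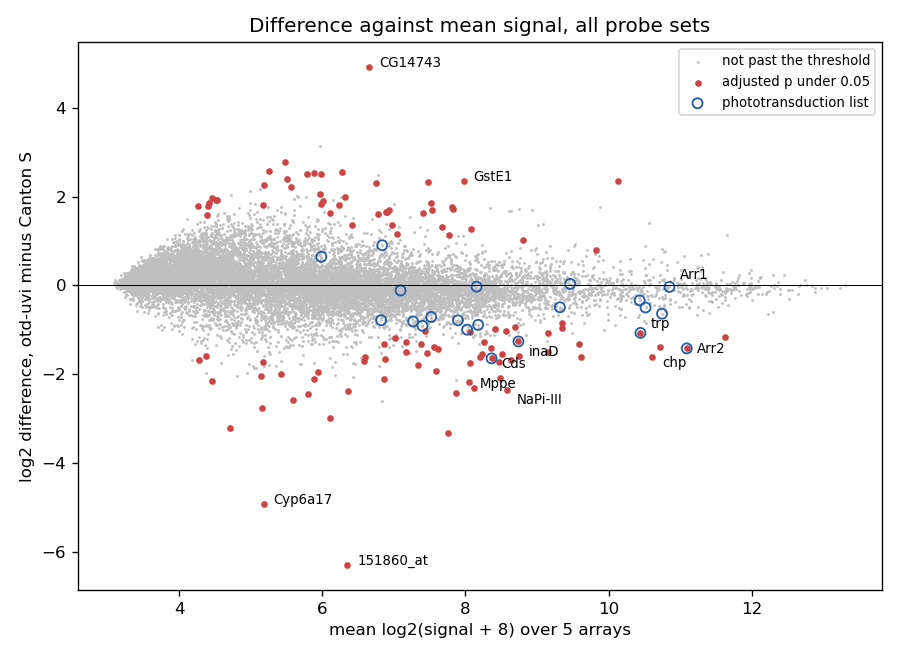
Log2 difference between otd-uvi and Canton S (vertical axis) against the mean log2 of signal plus 8 over 5 arrays (horizontal axis) for 13966 probe sets. Red points mark the 108 with an adjusted p under 0.05, and blue circles mark the 21 measured phototransduction genes, 18 of which lie below 0.

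The phototransduction list held 21 measured genes, and its median log2 difference was -0.71 (camera adjusted p = 9.9e-10). With an estimated correlation between its genes the list had an adjusted p = 0.64. Of the 21 genes 4 fell and none rose by limma over all probe sets, 16 had an unadjusted p under 0.05, and adjusted over the list alone 13 fell and 2 rose. Cds (153377_at), which makes the CDP-diacylglycerol needed to regenerate phosphoinositides, had a log2 difference of -1.64 (SE 0.15, adjusted p = 0.0107), with mean signals of 645 ± 4.91 in Canton S and 202 ± 24.1 in otd-uvi. Arr2 (143078_at), the major arrestin that ends rhodopsin signalling, went from 3938 ± 372 to 1469 ± 143, a log2 difference of -1.42 (SE 0.13, adjusted p = 0.0117). The scaffold protein gene inaD (143203_at) had a log2 difference of -1.26 (SE 0.13, adjusted p = 0.0127), and trp (143383_at), which encodes the main light-activated channel, one of -1.07 (SE 0.12, adjusted p = 0.0190). Other members of the cascade had values near 0: Arr1, the other arrestin, had a log2 difference of -0.03 (95% interval -0.40 to 0.33), and trpl, the other channel, one of 0.03 (95% interval -0.66 to 0.73). Both signs turned in several other settings, and without 1 array Arr1 ranged from -0.15 to 0.074 and trpl from -0.44 to 0.51. Gbeta76C, the beta subunit of the eye G protein, had a log2 difference of -0.64 (adjusted p = 0.0842). The 2 members that rose when adjusted over the list alone were laza, a lipid phosphatase gene, at 0.91 and Galphaq at 0.65, with adjusted p of 0.147 and 0.263 over all probe sets. They were named after their values were seen. Cds and Arr2 stayed past the threshold only without otd-uvi replicate 2 among the 5 fits that left out 1 array (log2 differences of -1.73 and -1.49), and inaD and trp in none of them. All 4 kept their direction in the 5 fits.

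**Figure D2:**
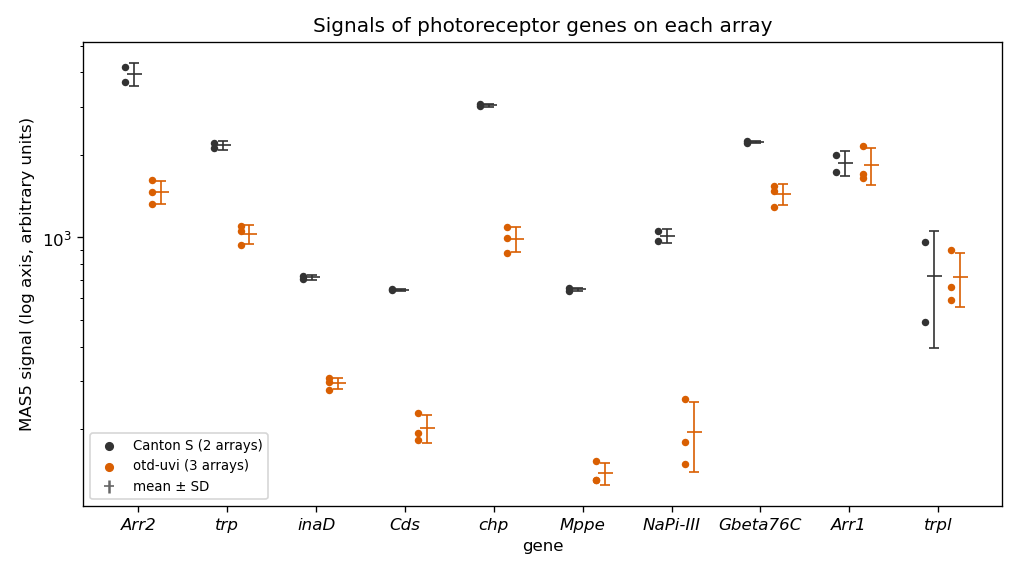
MAS5 signal on a log axis for 10 genes, with 1 point per array and the mean with its SD beside the points, for Canton S (black, 2 arrays) and otd-uvi (orange, 3 arrays). Arr2, trp, inaD, Cds, chp, Mppe and NaPi-III have every otd-uvi array below every Canton S array and an adjusted p under 0.05; Gbeta76C does not pass, and Arr1 and trpl overlap between groups.

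The list of rhabdomere and apical membrane genes, which build the light-sensing membrane stack, had 12 measured genes and a median log2 difference of -0.52 (camera adjusted p = 2.5e-05; adjusted p = 0.64 with an estimated correlation). One gene fell over all probe sets, and 3 fell and none rose adjusted over the list alone; 4 had an unadjusted p under 0.05. The gene that fell was chp (142652_at), from 3036 ± 40.5 to 989.7 ± 106, a log2 difference of -1.61 (SE 0.13, adjusted p = 0.00968). It stayed past the threshold without any 1 otd-uvi array (-1.69 to -1.53) and not without either Canton S array. Of the others, par-6, an apical polarity gene, had a log2 difference of -0.93 (adjusted p = 0.0856), prom one of -0.89 (adjusted p = 0.110) and kst, a heavy spectrin, one of -0.55 (adjusted p = 0.351).

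Neuronal markers (16 measured genes) had a median log2 difference of -0.47 (camera adjusted p = 4.5e-05; adjusted p = 0.64 with an estimated correlation). None passed over all probe sets by limma, 8 had an unadjusted p under 0.05, and 5 fell adjusted over the list alone. Of the 16 genes 14 were below 0. The 8 included Vmat, which went the other way, at 0.74 (adjusted p = 0.317). The largest differences were in VGlut, the vesicular glutamate transporter, at -1.49 (SE 0.43, adjusted p = 0.202), and in Syn, synapsin, at -1.24 (SE 0.22, adjusted p = 0.0650). The vesicle protein gene nSyb was at -0.93 (adjusted p = 0.122) and the pan-neuronal gene elav at -0.88 (adjusted p = 0.321). The list of the histamine cycle and the photoreceptor synapse (9 genes) had a median of -0.25 (camera adjusted p = 0.00316; adjusted p = 0.64 with an estimated correlation). None of its genes passed over all probe sets by limma, 3 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone. These were ort, a histamine-gated channel, at -1.22 (adjusted p = 0.0535) and t (tan), the enzyme that frees histamine from its conjugate, at -0.84 (adjusted p = 0.0712). The median was -0.42 without otd-uvi replicate 2 and -0.12 without otd-uvi replicate 3, and it lay at percentile 13.8 of random lists matched on signal and gene span. The next members were Balat at -0.58 (adjusted p = 0.404) and e (ebony), at -0.43 (adjusted p = 0.241). Alongside all 4 of these lists, the mean 3-prime to 5-prime ratio of the 3 controls was 1.41 and 1.37 in Canton S and 1.32, 1.68 and 1.88 in otd-uvi.

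The targeted gene oc (143425_at) did not pass the test. Its signals were 71.7 and 56.4 in Canton S and 27.6, 46.8 and 59.8 in otd-uvi, a log2 difference of -0.49 (SE 0.33, 95% interval -1.28 to 0.29, adjusted p = 0.527). Of the rhodopsins, the light receptors themselves, 1 had a probe set that names it alone: Rh7 (148637_at), at -0.03 (SE 0.26, adjusted p = 0.965). The 6 other rhodopsins on the list were not analysed here.

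The lists for the rest of the eye held no gene past the threshold by limma. Eye and photoreceptor transcription factors (23 genes, 3 with an unadjusted p under 0.05) had a median of -0.10 and a camera adjusted p = 0.348. Of them onecut, at -1.54 (adjusted p = 0.0712), fell adjusted over the list alone. Next came wts, which is on the list but encodes a kinase, at -1.16, bab1 at 0.80 and salm at -0.69, with adjusted p of 0.520, 0.355 and 0.294. Without Canton S replicate 2 the difference of wts was 0.03. Eye pigment genes (20 genes, 2 with an unadjusted p under 0.05) had a median of -0.03 and a camera adjusted p = 0.358. Their largest difference was cd at -1.24 (adjusted p = 0.119), followed by p at -0.44, rb at -0.44 and cm at 0.39 (adjusted p of 0.302, 0.516 and 0.341). Genes of the corneal lens and of pigment or cone cells (6 genes, none with an unadjusted p under 0.05) had a median of -0.11 and a camera adjusted p = 0.464. Here retinin, a lens protein gene, had a log2 difference of -0.41 with a 95% interval of -2.70 to 1.88. Cpr66D had one of -0.28 (adjusted p = 0.483), ct one of -0.21 (adjusted p = 0.733) and B-H1 one of 0.07 (adjusted p = 0.942). Retinoid and chromophore genes (7 genes, 3 with an unadjusted p under 0.05) had a median of -0.0043 and a camera adjusted p = 0.825.

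**Figure D3:**
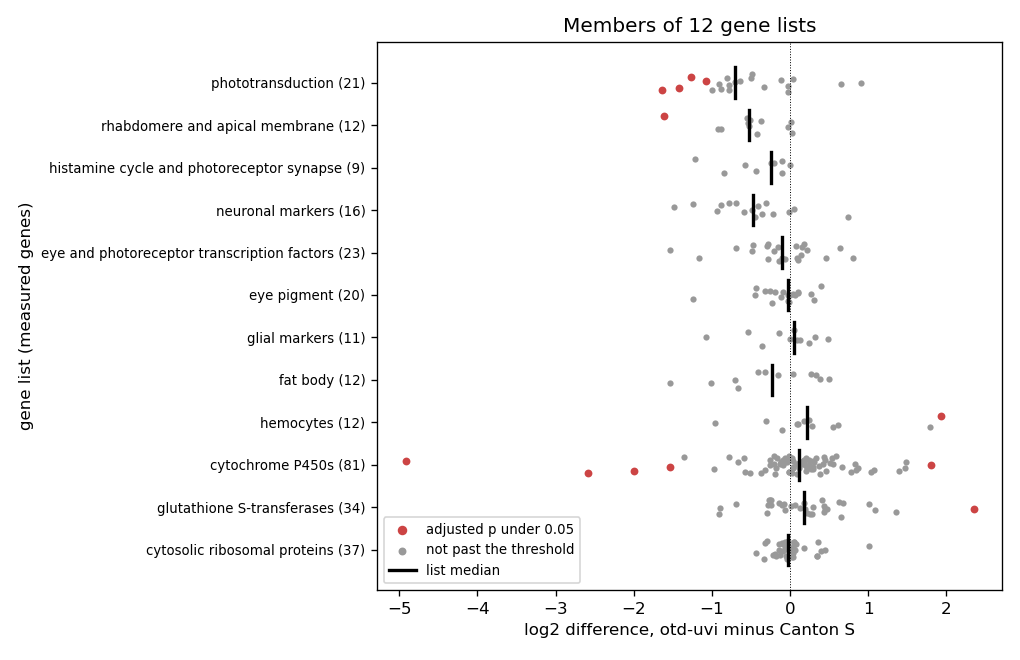
Log2 difference between otd-uvi and Canton S (horizontal axis) for each measured gene of 12 lists (vertical axis, number of genes in brackets). Red points have an adjusted p under 0.05 and black bars are list medians, the lowest being -0.71 for phototransduction.

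Detoxification genes held the largest single differences among the fixed lists. Of 81 cytochrome P450 genes 1 rose and 4 fell. An unadjusted p under 0.05 was reached by 17, and 4 rose and 6 fell adjusted over the list alone. The list as a whole did not pass (median 0.11, camera adjusted p = 0.796), and camera's direction turned under quantile normalization and cyclic loess. Cyp6a17 (152313_at), a P450 known from temperature preference, had signals of 275 ± 51.9 in Canton S and 1.27 ± 0.0787 in otd-uvi, under the control probe sets, and a log2 difference of -4.92 (SE 0.28, adjusted p = 0.00257). Cyp6a2 (143127_at), linked to insecticide resistance, was at -2.58 (SE 0.32, adjusted p = 0.0221), Cyp4p1 at -1.99 (SE 0.26, adjusted p = 0.0250) and Cyp12a4 at -1.53 (SE 0.15, adjusted p = 0.0127). Cyp4p3, the neighbour and close relative of Cyp4p1, was at 1.80 (SE 0.26, adjusted p = 0.0363) with a Canton S signal of 2.05 ± 0.103, under the control probe sets. Of 34 glutathione S-transferase genes GstE1 (152598_at) rose, from 87.1 ± 12.8 to 475.5 ± 48.6, a log2 difference of 2.35 (SE 0.17, adjusted p = 0.00497). In this list 8 had an unadjusted p under 0.05, and the list's median was 0.18 (camera adjusted p = 0.419). The next members, GstE7, GstD5 and GstE5, were at 1.36, 1.08 and 1.01 with adjusted p of 0.160, 0.151 and 0.249. Of these genes Cyp6a17 passed in all 5 fits without 1 array, and GstE1 only in the 3 fits without an otd-uvi array (2.28 to 2.42).

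Markers of other head tissues gave few calls. Of 12 hemocyte genes NimC1, a phagocytosis receptor of blood cells, rose by a log2 difference of 1.93 (SE 0.25, adjusted p = 0.0242), from 2.27 ± 0.300, under the control probe sets, to 31.2 ± 1.91. The list's median was 0.21 (camera adjusted p = 0.265). PPO2 was at 1.79 (adjusted p = 0.0886), crq at -0.96 (adjusted p = 0.170) and Pxn at 0.62 (adjusted p = 0.299). Among 9 sex-linked expression markers Sxl, the master regulator of female development, fell by both of its probe sets, at -1.54 (143373_at, adjusted p = 0.0267) and -1.27 (144641_at, adjusted p = 0.0467). Yp3 was at -1.54 (adjusted p = 0.0731), msl-2 at -0.84 (adjusted p = 0.288) and Yp2 at 0.39 (adjusted p = 0.543). The sex-linked list did not pass (camera adjusted p = 0.265). The testis transcripts Mst84Db and Mst84Dd, given below, rose. No sex of the heads was available here, so a different sex ratio of the groups cannot be told apart from other causes. Fat body genes (12 genes, median -0.24, camera adjusted p = 0.191) had no member past the threshold by limma and 2 with an unadjusted p under 0.05. Yp3 and the lipoprotein gene apolpp, at -1.01 (adjusted p = 0.0566), fell adjusted over the list alone. Lsp2 was at -0.71 and Fbp1 at -0.67 (adjusted p of 0.383 and 0.530). Without 1 array Lsp2 ranged from -0.98 to -0.38, Fbp1 from -1.11 to -0.22, msl-2 from -1.28 to -0.41 and Pxn from 0.29 to 0.94. Glial markers (11 genes, median 0.05, camera adjusted p = 0.464) had none past the threshold by limma and 2 with an unadjusted p under 0.05. Their largest differences were Eaat2 at -1.08 (adjusted p = 0.0934), Gs2 at -0.53 (adjusted p = 0.219), gcm at 0.48 (adjusted p = 0.341) and Gat at -0.36 (adjusted p = 0.355). The ecdysone receptor gene EcR fell by 1 probe set (146672_at, -2.04, adjusted p = 0.0263) and did not pass by its brighter one (154377_at, -0.73, adjusted p = 0.353).

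No other fixed list passed camera or held a gene past the threshold in limma by the probe set that stood for it. Genes with an unadjusted p under 0.05 numbered 3 of 18 for muscle (camera adjusted p = 0.742), 1 of 21 for antennal chemosensory genes (0.348), 1 of 16 for the ecdysone response (0.663), 5 of 20 for adult cuticle (0.742) and 0 of 6 for heat shock (0.348). They numbered 1 of 11 for the antimicrobial response (0.464), 1 of 12 for the circadian clock (0.427), 1 of 11 for cell death (0.742), 4 of 37 for cytosolic ribosomal proteins (0.464) and 5 of 39 for the proteasome (0.888). The largest medians among these lists were those of heat shock (0.55) and antennal chemosensory genes (0.31, with 16 of 21 above 0). Against the Canton S mean, the heat shock median was 0.85, 0.63 and 0.115 on otd-uvi arrays 1, 2 and 3. The median, the mean and the test differed in sign for 7 lists: retinoid, glial, muscle, sex-linked, cuticle, antimicrobial and ribosomal genes.

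Among genes outside these lists that rose, CG14743 (146831_at) was at 4.92 (SE 0.35, adjusted p = 0.00497), from 5.09 ± 1.19 to 409 ± 152. IFT54, an intraflagellar transport gene, was at 2.57 and Nop10, a gene of ribosomal RNA modification, at 2.27. The Canton S signals of CG14743, IFT54, CG1143 (2.41) and Nop10 were under the control probe sets, so their log2 differences are measured against background. The testis transcripts Mst84Db and Mst84Dd were at 2.54 and 2.31, the glucuronosyltransferase gene Ugt35B1 at 2.51, the cystathionine beta-synthase gene Cbs at 2.50, CG10953 at 2.36 and CG9150 at 2.32. Bili rose by 1 probe set (151569_at, 2.57, adjusted p = 0.0127), while its other probe set was at -0.74 (142435_at, adjusted p = 0.202). The 12 largest rises had adjusted p of 0.00497 to 0.0467. Of the 45 probe sets that rose, 12 had a Canton S signal under the control probe sets, and 11 of these had every otd-uvi array above the brightest control of that array.

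Among the largest falls outside the lists, Mppe (142664_at), a metallophosphoesterase that takes part in rhodopsin processing, went from 647 ± 9.34 to 138 ± 12.8, a log2 difference of -2.17 (SE 0.15, adjusted p = 0.00497). Another, dim probe set was at -0.29. NaPi-III, a phosphate transporter gene, went from 1015 ± 58.7 to 195 ± 56.4 (-2.36, SE 0.23, adjusted p = 0.0117). The acylphosphatase gene Acyp2 was at -3.21, fipi, an immunoglobulin-domain gene of the nervous system, at -2.99, the leucine-rich repeat gene kek2 at -2.43 and CG13920 at -2.38. Some genes fell by 1 probe set and had others that did not pass. For these, beat-VII, a guidance gene, was at -2.75 and -0.76, CG31145 at -2.44, -0.20 and -0.14, rhea (talin) at -2.31 and -0.49, and Dyb (dystrobrevin) at -2.15 and -0.38. Of the 63 probe sets that fell, 7 had otd-uvi signals under the control probe sets, those of Cyp6a17, Acyp2, beat-VII and Dyb among them, so their log2 differences are measured against background. The 12 largest falls among probe sets naming 1 gene had adjusted p of 0.00257 to 0.0467. The probe set 151860_at, which has no gene name and was named after its values were seen, went from 1117 ± 29.6 to 6.26 ± 1.39, also under the control probe sets (-6.31, SE 0.21, adjusted p = 0.00012). It passed in all 5 fits without 1 array.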

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

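Chosen after the results were seen were the tests of a shared loss of photoreceptors and of a shared response of detoxification genes, the counts that set aside genes known from other cells or not above the controls, the criterion that counts relatives once in the test of neighbours, the Fisher tests of lists, and the covariate for RNA integrity. The other tests of an explanation were set after the values of genes and lists had been seen and before their own results were.

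Of the control signals outside the main comparison, those whose otd-uvi mean exceeded the highest Canton S value were picked out. The actin ratio of 3-prime to 5-prime signal did not meet this rule (exact permutation test, two-sided p = 0.8). The log2 ratio of 3-prime to 5-prime signal averaged 1.74 in otd-uvi for GAPDH, against a highest Canton S value of 1.73, with 2 of 3 otd-uvi arrays above it (exact permutation test, two-sided p = 0.5). For eIF-4a it averaged 1.79 against a highest Canton S value of 1.46, also with 2 of 3 arrays above (exact permutation test, two-sided p = 0.3). The median signal of mouse and yeast controls averaged 7.39 in otd-uvi against a highest Canton S value of 3.69, with 3 of 3 arrays above (exact permutation test, two-sided p = 0.1, the smallest possible). The 3-prime to 5-prime ratio averaged over actin, GAPDH and eIF-4a was 1.41 and 1.37 in Canton S and 1.32, 1.68 and 1.88 in otd-uvi replicates 1, 2 and 3.

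The phototransduction list was lower in otd-uvi by camera with a preset correlation, and had an adjusted p = 0.64 with an estimated correlation. A shift of bright or long genes as the whole cause is argued against. Of 10000 random lists matched on mean signal and gene span, 0 percent had a median as low. Their own median was -0.15, so such a shift may make up part of the difference. The random genes were drawn independently, so the percentile takes no account of correlation within the list. Lower RNA integrity as the whole cause is argued against by the median of -0.65 with the ratio as a covariate (adjusted p = 3.6e-08 with the preset correlation). A loss of photoreceptors may contribute and cannot be told apart from an effect on single genes. Of 21 members 7 had a 95% interval wholly above the list median. The 4 called genes (trp, inaD, Arr2 and Cds) had one wholly below it. Of the 7, other cells also express 4 (Galphaq, inaE, laza and wun). With these set aside 3 remained (Ggamma30A, trpl and Arr1), and 1 to 2 without 1 array. Strain background also stays open, since each group was 1 strain.

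Neuronal markers were lower in otd-uvi as a list by camera with a preset correlation, though no member passed by limma over all probe sets. There 8 of 16 had an unadjusted p under 0.05, and these included Vmat, which was higher (0.74). With an estimated correlation the list had an adjusted p = 0.64. A shift of bright or long genes as the whole cause is argued against, since the list lay at percentile 0.51 of matched random lists. The histamine and synapse list lay at 13.8 of its own. The lists matched to neuronal markers had a median of -0.19 against -0.47, so such a shift may make up part of the difference. Here too the random genes were drawn independently, which takes no account of correlation within the list. RNA integrity as the whole cause is argued against by the median of -0.41 with the covariate (adjusted p = 0.00022 with the preset correlation). An effect of the mutation and strain background both stay open and were not tested apart.

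Called detoxification genes included a nearly complete loss of signal, that of Cyp6a17, and a gain from under the control probe sets, that of Cyp4p3. Of the called P450, GST and Ugt genes 3 were higher (Cyp4p3, GstE1 and Ugt35B1) and 4 lower. Cyp4p3 was not above the brightest control on every otd-uvi array. Without it 2 were higher and 4 lower, so a response in 1 direction does not cover all of them. These counts fell short of the 3 in each direction that the test asked for, so a shared response of some of them stays open. Strain variants in linked blocks may be a candidate source, but they were tested over all 93 called genes and not over detoxification genes alone. In a permutation test with 10000 random draws, 16 called genes had another called gene within 5 measured neighbours, against a median of 8 (p = 0.0272). With relatives counted once it was 12 against 7 (permutation p = 0.1402). Of the called P450, GST and Ugt genes only Cyp4p1 and Cyp4p3, neighbours of each other, had a called neighbour. The test therefore cannot decide for the others. This explanation and an effect of the mutation cannot be told apart. Cross-hybridisation between near relatives such as Cyp4p1 and Cyp4p3 was not tested.

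Called probe sets made up 6.17% of P450 genes and 0.743% of other genes (Fisher's exact test, p = 0.0053 adjusted over 25 lists). For phototransduction genes the shares were 19.0% and 0.748% (Fisher's exact test, p = 0.00048 adjusted over 25 lists). This test treats genes as independent. With an estimated correlation the phototransduction list had a camera adjusted p = 0.64.

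Of the 10 ways to split the 5 arrays into 2 and 3, 1 gave as many called probe sets, the real one with 108; the highest of the others gave 2. The splits are too few for a share under 0.05.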

How the results depend on the processing

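Cyclic loess and the covariate for RNA integrity were chosen after seeing the data. The 108 called probe sets kept their direction in each setting that tested them. Their number was 86 to 120 under 7 of the settings that keep all arrays, but 200 (81 higher, 119 lower) with the dimmest 40% left out, which tests fewer probe sets, 1 (0 higher, 1 lower; 1586 at an unadjusted p under 0.05) with the replicate number as a block, which leaves otd-uvi replicate 3 no weight, and 8 (3 higher, 5 lower) with the RNA covariate. Without the intensity trend 37 were lower and 49 higher. Leaving out 1 array gave 2 to 22 (0 to 6 higher, 2 to 16 lower), with 1272 to 2067 at an unadjusted p under 0.05; 2 probe sets passed in all 5 of these fits and 28 in at least 1. Samples of the 2 groups are linked by replicate number alone, and whether like numbers share a batch is not known. Deviations correlated across probe sets at -0.0045 for replicates 1 and 0.115 for replicates 2. The deviations of 2 Canton S arrays mirror each other, so these values cannot decide it.

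With an estimated correlation 0 of 24 lists passed (adjusted p = 0.64 for phototransduction, median -0.71, rhabdomere, -0.52, histamine, -0.25, and neurons, -0.47; unadjusted p of 0.0404, 0.110, 0.0871 and 0.0610). In all 16 other settings these 4 lists passed, with medians of -0.87 to -0.56, -0.66 to -0.40, -0.42 to -0.12 and -0.59 to -0.38. Each of these 16 kept the preset correlation, so they do not test that assumption. For oc the 15 alternatives gave -0.89 to -0.23, with a lowest adjusted p of 0.313.

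Some values that did not pass the test changed sign, and camera turned direction for the P450 list; the cause was not tested. Under quantile normalization B-H1 was -0.15 and Arr1 0.059, and under cyclic loess -0.11 and 0.047. Camera turned for the P450 list, whose median was 0.11, at medians of 0.019 (quantile), 0.027 (cyclic loess) and -0.056 (dimmest 40% left out), and without Canton S replicate 1 or otd-uvi replicate 1, where medians stayed above 0 (0.049 to 0.15 over the 5 fits). As a block the replicate number gave 0.14 for retinin and 0.039 for Arr1. The RNA covariate gave 0.96 for retinin, 0.017 for ct and -0.037 for trpl, and median centring gave -0.023 for trpl. Without 1 array retinin ranged from -1.53 to 0.71, B-H1 from -0.24 to 0.38, wts from -2.35 to 0.027, Arr1 from -0.15 to 0.074, trpl from -0.44 to 0.51, and Rh7 from -0.13 to 0.064. Without turning sign, others also moved by over 1.5 times: kst from -0.76 to -0.33, rb from -0.57 to -0.24, Cpr66D from -0.47 to -0.083, ct from -0.39 to -0.081, bab1 from 0.49 to 1.11, Balat from -0.80 to -0.33, elav from -1.10 to -0.53, Gs2 from -0.74 to -0.33, Gat from -0.43 to -0.22, Yp2 from 0.24 to 0.54 and oc from -0.70 to -0.23, as did Lsp2, Fbp1, msl-2 and Pxn. Over 81 probe sets, 937 of 1204 values kept direction and side of the threshold, 235 lost the call, 11 gained it and 21 changed sign. Only probe sets called in the main fit could lose the call. The share kept is therefore raised by genes that had not passed (46 with oc, which is not among the 81). The number of arrays and signal over background limit these values, and 2167 probe sets were under the controls on all 5 arrays.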

Other observations

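The genes in this part were chosen after their values were seen, as was the Fisher test of genes near oc, and no test of them as groups was run. They are single called genes outside the rule for named genes. Cpn, calphotin, a calcium-binding protein of photoreceptors, went from 824 ± 135 to 273 ± 60.4, a log2 difference of -1.58 (SE 0.21, adjusted p = 0.0267). The calcium-activated potassium channel gene slo fell by 1.62 on the log2 scale (SE 0.25, adjusted p = 0.0437), and Slob, whose product binds that channel, fell by 1.74 (SE 0.18, adjusted p = 0.0147) in 1 probe set and was at -0.46 (adjusted p = 0.477) in another. Orai, a calcium channel gene, was at -1.20 (adjusted p = 0.0371), and Cngl, a cyclic nucleotide-gated channel-like gene, at -1.74 (adjusted p = 0.0437) with a second probe set at 0.05. The octopamine receptor gene Octalpha2R was at -2.10 (adjusted p = 0.0284). Of genes that rose, Axs, an anoctamin relative, was at 1.63 (adjusted p = 0.0263) and Nmda1 (locus CG3798) at 1.70 (adjusted p = 0.0149).

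Near oc, 1 of its 100 closest measured neighbours was called, against 0.86% of other genes (Fisher's exact test, p = 0.581).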
